A study of Mus musculus with 6 samples.

How the data were processed

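The series holds 6 RNA-seq libraries of mouse splenic B cells, 3 labelled KO for Gps2 and 3 labelled WT. Per the labels' protocols, floxed Gps2 mice were crossed with heterozygous 129sv CD19-cre mice, and B cells were isolated from splenocytes by magnetic depletion with a pan-B kit, with purity checked by flow cytometry for CD19 and CD3. Total RNA was made into cDNA libraries either with the NEBNext Ultra Directional kit or with the TruSeq Stranded total RNA kit after rRNA depletion by RiboZero Gold, and sequenced on a HiSeq2500 with 50 bp single reads. The labels do not say which library was made with which kit, give no age or sex, and do not say whether the WT mice carried the Cre allele.

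The authors deposited 1 table of RPKM values, in which reads are scaled to the length of the transcript in kilobases and to the depth of the library, with 22723 RefSeq transcripts and 1 per gene symbol. Bowtie, HOMER and the genome build mm8 are named in the submitters' processing notes, without versions, and the table's name and column names give HOMER and RPKM. The strand setting, filters and the handling of reads that match several places are not stated, so genes with near-identical copies and overlapping or antisense genes are uncertain. The columns for transcript length, start, end and number of copies in the genome were deposited beside the RPKM values and were used as given, and 90 transcripts had more than 1 copy. Coordinates are those of the table.

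Each deposited value times the transcript length was a whole multiple of 1 step per library, within a tolerance of 0.1 read, for 100% of the values of up to 100 reads whose rounding to 3 decimals allowed the check. The step is the value of 1 read, from 0.0290 RPM in WT 12 to 0.0595 in KO g84, and its inverse gave the depth of each library. Whole reads per transcript were recovered in this way for the voom fits only. Depth was 16.8 to 34.5 M reads, of which 10.4 to 16.8 M fell in the listed transcripts. A read is the smallest difference a library can show, and PCR copies cannot be told from separate molecules, so depth covers counting error only.

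Values were tested as log2(RPKM + 0.5), for 11676 genes with at least 0.5 RPKM in at least 3 of the 6 libraries, which left out 11047. The main test was limma's moderated test with a mean-variance trend, two-sided, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05 (limma 3.58.1 in R 4.3.3). For Gps2 and Cd19 an exact permutation test of the group difference on the log2 scale was added, with 20 assignments and a smallest p of 0.1. Gene lists were tested with camera with a preset correlation of 0.01, where a list had at least 4 tested members, and again with an estimated correlation and with fry. Adjustment was over the 31 lists tested. Camera compares a list with all other genes, while fry asks whether the genes of a list move 1 way on balance. Of the listed genes, 20 were not found in the table. Lists share members, and the number shared with another list was 0 of 19 for T cells, 0 of 15 for neutrophils, 1 of 31 for proliferation, 2 of 14 for transitional B cells and 1 of 21 for antigen presentation.

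The titles of the 2 genotypes share only the tag g84. A block of 3 assumed pairs, 12 with 13, 26 with 27 and g84 with g84, was written as an alternative before the data were examined. After median centring, the deviations of the libraries from their group means were correlated across genes at r = 0.738, 0.768 and 0.865 within these pairs. In each case the assumed partner was the library of the other genotype with the highest r. Genes are not independent replicates, and the labels do not state the pairs. Values from this block are given beside a result where they change its call.

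The test, the filter, the groups, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Gps2 and Cd19, then the 10 genes of each direction with the largest change among those past the threshold, or, where fewer than 5 passed, the 5 with the smallest p and a mean of at least 1 RPKM in the higher group. It also named up to 2 members of each list with no member past the threshold, and the 2 most abundant members of the lists of other cell types. For the NK, megakaryocyte, dendritic, erythroid and stromal lists, for heat shock genes and for non-polyadenylated RNA no member is named, and for some other lists 1. Ms4a6b, Sh2b2, Abcb10, Gpr183, Cxxc5 and Gdpd3 were named after their values were seen. Genes at least 1.5-fold apart in the same direction in every assumed pair were counted among 10749 genes, those with a mean of at least 1 RPKM in 1 group, and the count was repeated with each pair turned round.

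Alternatives covered the pseudocount (0.1 and 1 RPKM), the filter (none, and a mean of at least 2 RPKM), the scaling (values rescaled to 1 total, median centring, quantile normalization), the test (no trend, robust, sample quality weights), a term for the g84 libraries, the block of assumed pairs, leaving out each library, and leaving out the sex-linked, immunoglobulin and haemoglobin genes. Added after the data were examined were the block with median centring, voom on recovered reads with and without the block, fits without both g84 libraries and without KO g84, and the list tests with the block.

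The fits were tested on simulated libraries with 200 changed genes and the depth of the real ones. Reads were drawn around the mean of each assumed pair, with a dispersion of 0.02. For the run without differences between the series, the mean of all libraries was used. The pairs thus held by construction, with no difference within a pair beyond this spread and the simulated changes. The shares called with the block therefore do not describe libraries that differ within a pair in other ways. In the comparison of KO and WT simulated with the differences between the series of libraries, the fit with genotype alone called 0% of the genes changed 1.5-, 2- and 4-fold, with 0 false calls among 11695 genes. The block of pairs called 23.7, 88.7 and 100% of them with 63 false calls, the block with median centring 18.6, 83.1 and 100% with 20 false calls, and voom with the block 35.6, 93.0 and 100% with 4 false calls. Simulated without those differences, the fit with genotype alone called 15.3, 83.6 and 100% of them, with 11 false calls among 13367 genes. A simulated list of 30 genes raised 1.5-fold was called by camera with the preset correlation in all fits, and with an estimated correlation it had an adjusted p of 0.0663 with genotype alone, 0.0911 with the pairs, 0.0476 with the pairs and median centring, 0.049 by voom with the pairs, and 0.000598 with genotype alone when simulated without those differences.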

Results

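RNA-seq was deposited for splenic B cells of mice that lack Gps2 in B cells and of wild-type (WT) mice, with 3 libraries in each group. The knockout (KO) was made by crossing floxed Gps2 mice to heterozygous CD19-cre mice, in which the Cre recombinase is expressed from the Cd19 gene, per the labels' protocols. GPS2 is a subunit of the NCoR/SMRT corepressor complex, and the title of the series names it as an inhibitor of the ubiquitin-conjugating enzyme UBC13. B cells were purified by magnetic depletion of other splenocytes. The KO libraries carry the tags 13, 26 and g84 and the WT libraries 12, 27 and g84. Sequencing depth, recovered from the deposited values, was 34.5 M reads in WT 12, 25.3 M in WT 27, 22.2 M in WT g84, 30.7 M in KO 13, 29.5 M in KO 26 and 16.8 M in KO g84. The 4 numbered libraries had 33.8 to 46.1% of their reads in the listed transcripts, and the 2 g84 libraries 73.9 and 75.3%. From 2.95 to 7.46% of genes were listed at 0 in the numbered libraries, against 32.4 and 32.6% in the g84 libraries. The first principal component of log2 RPKM, after median centring, separated these series of libraries and held 72.7% of the variance. The pairs 12 with 13, 27 with 26, and g84 with g84 were assumed from the titles before the data were examined, and each library deviated from its group mean most like its assumed partner. The p-values below measure the spread between these libraries, since the labels do not say that each came from a different mouse. Fold changes are on the scale of log2(RPKM + 0.5), which understates those of low genes.

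Gps2 was lower in all 3 KO libraries than in any WT library, which is the direction that the labels require. Its mean was 13.2 ± 6.51 RPKM (SD, n = 3) in KO and 41.6 ± 23.6 RPKM (SD, n = 3) in WT, 3.0-fold lower in KO. The WT libraries 12, 27 and g84 held 28.0, 28.0 and 68.9 RPKM, and the KO libraries 13, 26 and g84 held 8.56, 10.4 and 20.6 RPKM. KO over WT was 0.306, 0.370 and 0.299 in the 3 assumed pairs. The labels do not state which part of the gene is deleted, so these values cover the whole transcript NM_019726, at 69730387 to 69732786 on chromosome 11 (mm8). The log2 difference was -1.59 (SE 0.54), with an adjusted p of 1.0 in the limma fit with genotype alone. With a block of the 3 assumed pairs the SE was 0.092 and the adjusted p was 0.0421. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow.

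Cd19, the B cell coreceptor gene that carries the Cre insertion in these mice, was lower in KO in each assumed pair. Its mean was 140 ± 90.1 RPKM (SD, n = 3) in KO and 274 ± 185 RPKM (SD, n = 3) in WT, 1.94-fold lower in KO. KO over WT was 0.483, 0.566 and 0.497 in the pairs 12 with 13, 27 with 26, and g84 with g84. The transcript NM_009844 lies at 126199596 to 126206018 on chromosome 7. The log2 difference was -0.96 (SE 0.70), with an adjusted p of 1.0 by limma with genotype alone and 0.0903 with the pairs. It passed in limma's voom fit with the pairs, with an adjusted p of 0.0171. With 1 library left out the log2 difference lay between -1.45 (without KO g84) and -0.44 (without WT g84). The groups overlapped, and the exact two-sided permutation test gave p = 0.3.

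**Figure D1:**
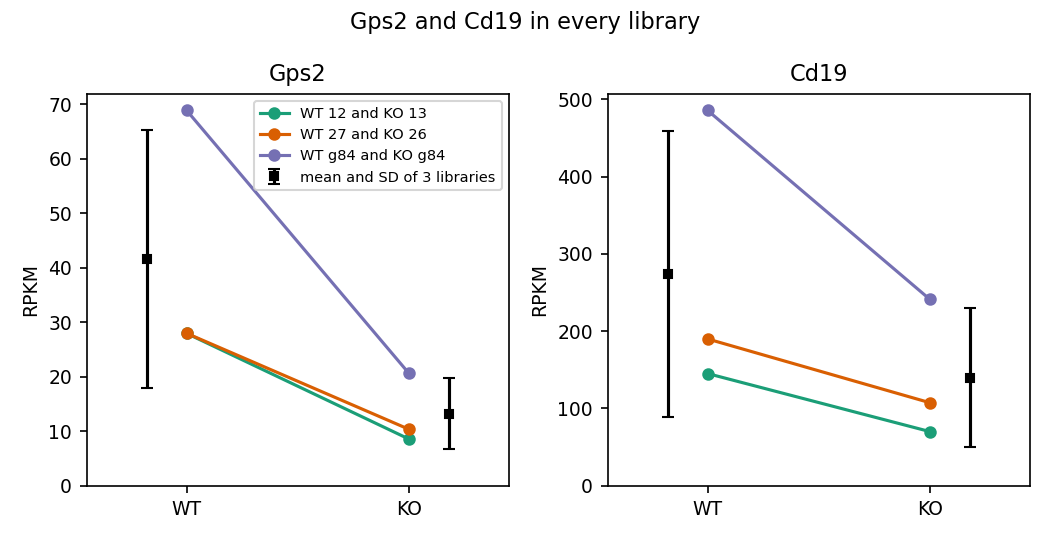
RPKM of Gps2 and Cd19 in each library, with lines joining the assumed pairs and black squares with bars for the mean and SD of the 3 libraries of a genotype. Gps2 lies between 8.56 and 20.6 RPKM in KO and between 28.0 and 68.9 RPKM in WT, and Cd19 is lower in KO in each pair.

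The comparison of all genes asks which transcripts differ in B cells without GPS2. Higher in KO were Cd36, a scavenger receptor and fatty acid transporter, at 46.2 ± 16.5 against 15.7 ± 4.55 RPKM, and Nedd4, a ubiquitin ligase, at 9.89 ± 3.04 against 4.0 ± 0.41 RPKM (SD, n = 3 each). Lamp3, a lysosomal membrane protein, stood at 4.39 ± 1.27 against 1.62 ± 0.29 RPKM, and Rgs13, a regulator of G protein signalling, at 1.19 ± 0.73 against 0.28 ± 0.20 RPKM. The microRNA gene Mir5132 completed the 5 genes with the smallest p in this direction, at 1.52 ± 0.16 against 0.38 ± 0.65 RPKM. Its transcript is short, at 70276248 to 70276318 on chromosome X, so its values rest on at most a few reads per library. Mir5132 was listed at 0 in WT 12 and WT g84. Its log2 ratio was 1.92 in the pair 12 with 13, 0.26 in 27 with 26 and 2.14 in g84. The log2 differences were 1.49 (SE 0.50) for Cd36, 1.17 (SE 0.40) for Nedd4, 1.18 (SE 0.37) for Lamp3, 1.06 (SE 0.34) for Rgs13 and 1.44 (SE 0.43) for Mir5132. Lower in KO, with the smallest p, were Gm15880, a transcript of chromosome 7 with no known function, at 0.96 ± 0.059 against 3.64 ± 2.06 RPKM, and 4 genes of chromosome 11. All of these genes had an adjusted p of 1.0 by limma with genotype alone, except Snord1c with 0.442, so none passed. Dtx1, a regulator of Notch signalling, was lower as well, at 22.5 ± 17.2 against 42.5 ± 26.6 RPKM, a log2 difference of -0.98 (SE 0.62).

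By limma with genotype alone, 0 of 11676 genes passed an adjusted p of 0.05, 0 higher and 0 lower in KO. At an unadjusted p under 0.05 there were 34 genes (18 higher, 16 lower), where chance gives 584. The block of assumed pairs gave 1 gene, Gps2, lower, and 2784 genes (356 higher, 2428 lower) at an unadjusted p under 0.05. With median centring as well, added after the data were examined, it gave 4 genes: Cd36 (adjusted p = 0.0166), Ms4a6b (0.0166) and Hmox1 (0.0324) higher and Gps2 (0.0166) lower. The genes at an unadjusted p under 0.05 were then 899 higher and 917 lower. Voom on the recovered reads, added after the data were examined, gave 0 genes without the pairs (192 unadjusted) and 120 with them, 90 higher and 30 lower. In that fit Cd36 (adjusted p = 0.000221), Nedd4 (0.00157), Lamp3 (0.00465), Rgs13 (0.0390), Gm15880 (0.0456) and Dtx1 (0.0117) passed, and Mir5132 did not (0.286). Counted without a test, 43 of 10749 genes were at least 1.5-fold apart in the same direction in each of the 3 pairs, 10 higher and 33 lower. The same count with 1 pair turned round was 5, 7 and 7. The ratios were not centred, and their median over all tested genes was -0.16 in the pair 12 with 13, -0.11 in 27 with 26 and -0.066 in g84. This offset favours lower genes, and it no longer runs 1 way when a pair is turned round. Scaling may thus enter both contrasts. Of the 43 genes, 29 were among the 120 of the voom fit. Without KO g84, which leaves WT g84 with no partner, voom with the pairs gave 275 genes (207 higher, 68 lower). The genotype difference in that fit rested on the pairs 12 with 13 and 27 with 26 alone. Without WT g84, limma with genotype alone gave 9 genes (6 higher, 3 lower), without KO 26 it gave 2 and without WT 12 it gave 1.

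**Figure D2:**
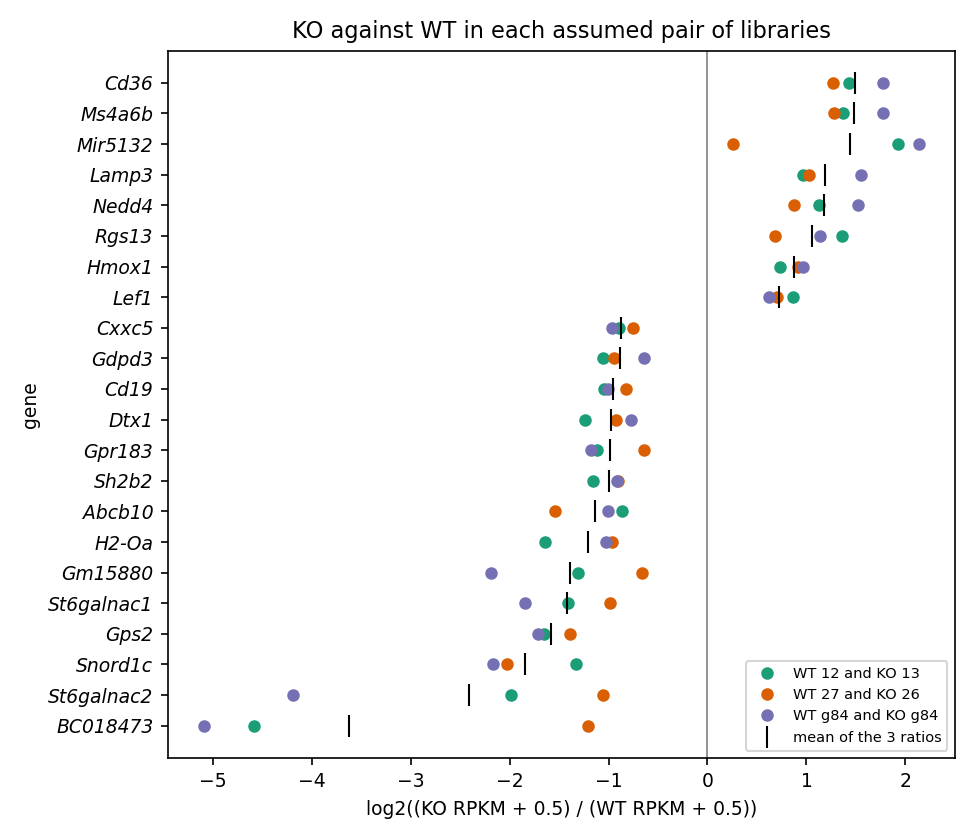
Log2 ratio of KO to WT RPKM, after adding 0.5 to both, for 22 genes in each assumed pair of libraries, with a black bar at the mean of the 3 ratios. The 3 ratios of a gene lie on the same side of 0, and those of BC018473 and St6galnac2 lie farther from 0 in the pairs 12 with 13 and g84 with g84 than in the pair 27 with 26.

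The 4 genes of chromosome 11 lie between 116488595 and 116591597 (mm8), and Snord1b and Snord1a, which lie among them, did not follow genotype in every pair. They are the small nucleolar RNA gene Snord1c (NR_028569), the sialyltransferase genes St6galnac2 (NM_009180) and St6galnac1 (NM_011371), and the non-coding BC018473 (NR_003364). Snord1c stood at 1.35 ± 0.53 RPKM (SD, n = 3) in WT and was listed at 0 in the 3 KO libraries, a contrast of 2, 3 and 3 recovered reads in WT 12, 27 and g84 with 0 in KO. BC018473 stood at 11.7, 27.03 and 16.6 RPKM in WT 12, 27 and g84, at 11.4 RPKM in KO 26, at 0.010 RPKM in KO 13 and at 0 in KO g84. St6galnac2 stood at 3.84, 8.27 and 9.18 RPKM in the same WT libraries, at 3.72 RPKM in KO 26, 0.60 RPKM in KO 13 and 0.029 RPKM in KO g84. St6galnac1 was at 1.51 ± 0.46 RPKM in WT and 0.31 ± 0.42 RPKM in KO (SD, n = 3), a log2 difference of -1.42 (SE 0.37). The log2 differences of St6galnac2 and BC018473 were -2.41 (SE 0.66) and -3.63 (SE 1.0). Over the 4 genes the median log2 ratio was -1.70 in the pair 12 with 13, -1.13 in 27 with 26 and -3.18 in g84, and over 10 neighbouring genes it was -0.36, 0.010 and -0.31. Snord1c lies inside the longer transcript 1810032O08Rik on the same strand, so its reads cannot be told apart from reads of that transcript. None of the 4 passed by limma with genotype alone, with the pairs (adjusted p from 0.105 to 0.122) or by voom with the pairs (0.134 to 0.329). Over all alternatives, BC018473 and St6galnac2 each passed in 3 of 24, Snord1c in 2 of 23 and St6galnac1 in 1 of 23. Some of these passes came by limma with genotype alone when 1 library was left out. Without WT g84 the adjusted p was 0.000705 for BC018473 and for Snord1c and 0.0440 for St6galnac2. Without KO 26 it was 1.70e-05 for BC018473 and 0.0132 for St6galnac2, and without WT 12 it was 0.0170 for Snord1c.

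Of 34 gene lists fixed before the data were examined, 31 had enough tested members. With camera's preset correlation, 9 lists lay higher in KO and 3 lower, and 0 did so with an estimated correlation (lowest adjusted p = 0.397) or by fry. The block of pairs gave 16 lists, 10 of them among the 12, and 0 with an estimated correlation (lowest adjusted p = 0.487). Gps2 and Cd19 were left out of the lists. No list member passed over all genes by limma with genotype alone or with the pairs, so single genes are given as values. The median log2 fold change over all tested genes was -0.11 (0.00 after median centring), and list medians are given relative to it unless stated otherwise. Counts of higher and lower members are not relative to it, so they lean towards lower. The fit with the pairs was not centred either, with 356 genes higher and 2428 lower at an unadjusted p under 0.05. Its counts adjusted over a list alone lean the same way. By voom with the pairs, 0 members of the ribosomal, B cell receptor, follicular, NF-kB and survival lists passed as lower over all genes.

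Transitional and precursor B cell genes lay higher in KO, with 11 of 14 tested members higher and a relative median of 0.42. Lef1, a transcription factor of lymphocyte precursors, stood at 5.502 ± 1.79 RPKM in KO and 3.14 ± 1.16 RPKM in WT, at least 1.54-fold higher in each pair, and passed by voom with the pairs (adjusted p = 0.0220). Sox4 stood at 1.67 ± 0.29 against 1.19 ± 0.39 RPKM and Il7r, the interleukin 7 receptor gene, at 5.21 ± 2.56 against 3.95 ± 3.02 RPKM (SD, n = 3 each). Camera gave an adjusted p of 4.31e-06 with the preset correlation and adjusted p = 0.397 with an estimated correlation. Adjusted over the list alone, 0 members passed with genotype alone, and 5 higher and 1 lower with the pairs. The list was no longer called without WT g84 (relative median 0.11, adjusted p = 0.162), its median was 0.15 without KO 26 and 0.62 without KO g84, and Il7r turned to -0.66 with sample quality weights. T cell genes were also higher in KO, with a relative median of 0.59. The 2 lists share no member, but that does not make them independent. In the pairs 12 with 13, 27 with 26 and g84 the relative medians were 0.42, 0.23 and 0.49 for this list. For T cell genes they were 0.63, 0.32 and 0.53. Within each genotype, Lef1 and Il7r were highest in WT 27 and KO 26. So were the T cell genes Cd3d, Cd3g, Cd28, Itk, Tcf7 and Lat, while Cd3e and Cd247 were highest in the g84 libraries. T cells left after the isolation were therefore not separated from a change in the B cells.

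Among lists of mature B cell stages the relative median was -0.10 for follicular, 0.02 for marginal zone and 0.14 for germinal centre genes. That of the transitional list was 0.42, and no test compared the lists. Follicular B cell genes had 10 of 14 members lower, among them Sell, the homing receptor L-selectin, at 139 ± 53.6 against 193 ± 61.2 RPKM, and Bcl2 at 7.88 ± 3.24 against 11.6 ± 2.77 RPKM. Cd200 stood at 9.30 ± 4.52 in KO and 14.6 ± 8.34 RPKM in WT (SD, n = 3 each). The list was not called (adjusted p = 0.241 by camera, relative median -0.10), and adjusted over the list alone 5 members passed, all lower, with the pairs. Marginal zone B cell genes, to which Dtx1 and Cd36 belong, had 9 members higher and 18 lower and were not called (adjusted p = 0.410). Germinal centre and switched B cell genes, with Rgs13 and S1pr2 (1.88 ± 0.79 against 1.39 ± 0.47 RPKM), had 5 of 8 members higher. That list was called by camera (adjusted p = 0.0168), but with adjusted p = 0.678 with an estimated correlation and 0.0597 with the pairs. It was lost as well with a term for the g84 libraries (0.121), with median centring (0.210), by voom with the pairs (0.143), and without WT 12 (0.0807), WT g84 (0.200), KO g84 (0.0645) or both g84 libraries (0.173).

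Plasma cell and secretory genes, B-1 cell genes and age-associated B cell genes were called higher with the pairs but not with genotype alone. With an estimated correlation and the pairs all 3 lists had an adjusted p of 0.75. Of the plasma cell list 15 of 25 members were higher (camera adjusted p = 0.0806 with genotype alone and 0.00211 with the pairs), with Xbp1 at 83.3 ± 49.3 against 57.1 ± 34.5 RPKM and Tnfrsf17 at 0.83 ± 0.69 against 0.40 ± 0.14 RPKM (SD, n = 3 each). The B-1 list had 10 of 19 members higher (0.196 and 0.0389) and the age-associated list 6 of 10 (0.241 and 0.0389). Both had their highest median log2 ratio in the g84 pair, where neutrophil genes were high as well. Their median log2 ratios in the pairs 12 with 13, 27 with 26, and g84 were -0.16, -0.07 and 0.32 for B-1 and -0.06, -0.34 and 0.75 for age-associated genes. These are not relative to all genes, whose medians were -0.16, -0.11 and -0.066. Against those, B-1 genes lay close in 12 with 13 and 27 with 26 and above in g84. Age-associated genes lay above in 12 with 13 and g84 and below in 27 with 26. The B-1 member Itgam, which myeloid cells also express, stood at 8.88 RPKM in KO g84 and 1.93 RPKM in WT g84. Tbx21, which belongs to both of these lists, stood at 1.30 ± 0.18 RPKM in KO and 2.15 ± 0.84 RPKM in WT. With genotype alone the plasma cell list was called after median centring (0.0339) and without WT g84 (0.000119) or KO 26 (1.95e-06), the B-1 list without KO 13 (0.0139) and the age-associated list without WT 27 (0.00914). The pair 27 with 26 moved against the other pairs in the plasma cell list. The median log2 ratios of that list, also not relative to all genes, were 0.33, -0.20 and 0.06.

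The lists chosen for what GPS2 is known to bind, UBC13 and the NCoR/SMRT corepressor, were not called by camera with genotype alone. All 24 tested genes of UBC13 and K63-linked ubiquitination were lower in KO, but their relative median was -0.06. Ube2n, which encodes UBC13, stood at 2.05 ± 0.48 RPKM in KO and 2.65 ± 0.87 RPKM in WT, and its partner Ube2v2 at 1.38 ± 0.046 against 1.81 ± 0.34 RPKM (SD, n = 3 each). Camera gave an adjusted p of 0.104 with genotype alone and 0.0389 with the pairs, and adjusted p = 0.940 and 0.75 with an estimated correlation. The NCoR/SMRT corepressor partners had 9 of 12 members lower and a relative median of 0.00 (camera adjusted p = 0.896), with Tbl1xr1 at 16.9 ± 3.46 against 21.2 ± 0.80 RPKM. NF-kB target genes had 20 of 29 members lower (0.655), with the survival gene Bcl2a1b at 10.8 ± 6.19 against 15.4 ± 6.26 RPKM and the cell cycle gene Ccnd2 at 31.6 ± 18.2 against 19.4 ± 7.75 RPKM. Ccnd2 passed by voom with the pairs (adjusted p = 0.0220). Adjusted over the list alone with the pairs, 1 NF-kB target passed as higher and 8 as lower.

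Genes of TLR and JNK signalling had 20 of 25 members lower (camera adjusted p = 0.421), with Ly86 at 70.3 ± 38.9 against 102 ± 43.7 RPKM and Tlr6 at 4.91 ± 2.02 against 6.56 ± 2.55 RPKM (SD, n = 3 each). B cell receptor signalling had 24 of 26 members lower and a relative median of -0.11, with Blk at 80.8 ± 45.5 against 106 ± 56.8 RPKM and Card11 at 18.4 ± 11.7 against 22.7 ± 10.2 RPKM. Its camera adjusted p was 0.236 with genotype alone and 0.0135 with the pairs, and 5 members, all lower, passed adjusted over the list alone with the pairs. With an estimated correlation it had adjusted p = 0.940 and 0.75. Without WT g84 the sign of Blk turned (0.015). FOXO1 targets and PI3K-AKT genes had 19 of 24 members lower (0.370), Il7r and Sell among the members.

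Proliferation genes were higher in KO, with 29 of 31 tested members higher and a relative median of 0.47. Mki67, a marker of cycling cells, stood at 18.6 ± 9.51 RPKM in KO and 8.85 ± 4.22 RPKM in WT, and the kinetochore gene Cenpf at 1.77 ± 1.05 against 0.87 ± 0.34 RPKM (SD, n = 3 each). By voom with the pairs 7 members passed, all higher, with an adjusted p of 0.0387 for Mki67 and 0.0326 for Cenpf. Camera gave an adjusted p of 4.50e-14, and adjusted p = 0.706 with an estimated correlation. Adjusted over the list alone, 0 members passed in either limma fit. The relative median was 0.63 in the pair 12 with 13, 0.10 in 27 with 26 and 0.66 in g84, with 30, 20 and 30 members higher. With 1 library left out it was 0.24 without KO 13, 0.30 without WT 27, 0.34 without KO g84 and 0.85 without KO 26, and the list stayed called. Neutrophil genes were higher in the g84 pair (relative median 2.89) and T cell genes in all 3 pairs (0.63, 0.32 and 0.53).

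Targets of p53 were higher in KO, with 11 of 14 members higher and a relative median of 0.27. Gtse1 stood at 5.44 ± 3.48 against 3.15 ± 1.65 RPKM and passed by voom with the pairs (adjusted p = 0.0246), and Plk2 stood at 3.65 ± 0.77 against 2.36 ± 0.12 RPKM (SD, n = 3 each). Both encode proteins of the cell division cycle. Camera gave an adjusted p of 0.000338, and adjusted p = 0.940 with an estimated correlation. The call was lost without KO g84 (relative median 0.17, adjusted p = 0.104) or without WT 27 (0.19 and 0.279), and adjusted over the list alone 3 members, all higher, passed with the pairs. Survival and apoptosis genes had 19 of 21 members lower, a relative median of -0.02 and no call (0.295), with Bcl2 and Bcl2a1b among the 3 that passed as lower, adjusted over the list alone, with the pairs.

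Antigen presentation genes were lower in KO, with 18 of 21 members lower and a relative median of -0.26. H2-Oa, a subunit of the MHC class II accessory molecule H2-O, stood at 18.6 ± 11.5 RPKM in KO and 40.5 ± 19.6 RPKM in WT, at least 1.95-fold lower in each pair, and passed by voom with the pairs (adjusted p = 0.0171). The class II gene H2-Eb2 stood at 8.84 ± 5.25 against 17.2 ± 2.95 RPKM (SD, n = 3 each). Camera gave an adjusted p of 0.000902, and adjusted p = 0.940 with an estimated correlation. Adjusted over the list alone, 0 members passed with genotype alone and 9, all lower, with the pairs. The call was lost with a term for the g84 libraries (0.147), without both of them (0.0659), without KO 13 (0.233) and without WT 27 (0.268). The relative median was -0.06 without KO 13, -0.17 without WT 27 and -0.43 without WT 12. Genes of the MHC region on chromosome 17 differed in presence between the libraries. H2-Ea-ps, chosen after its values were seen, stood at 477 RPKM in KO 13, 1086 RPKM in WT g84 and 914 RPKM in KO g84, and between 0.22 and 0.51 RPKM in WT 12, WT 27 and KO 26. By pair, the relative median of the list was -0.34 in 12 with 13, where H2-Ea-ps differed, and -0.29 and -0.20 in the other pairs.

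**Figure D3:**
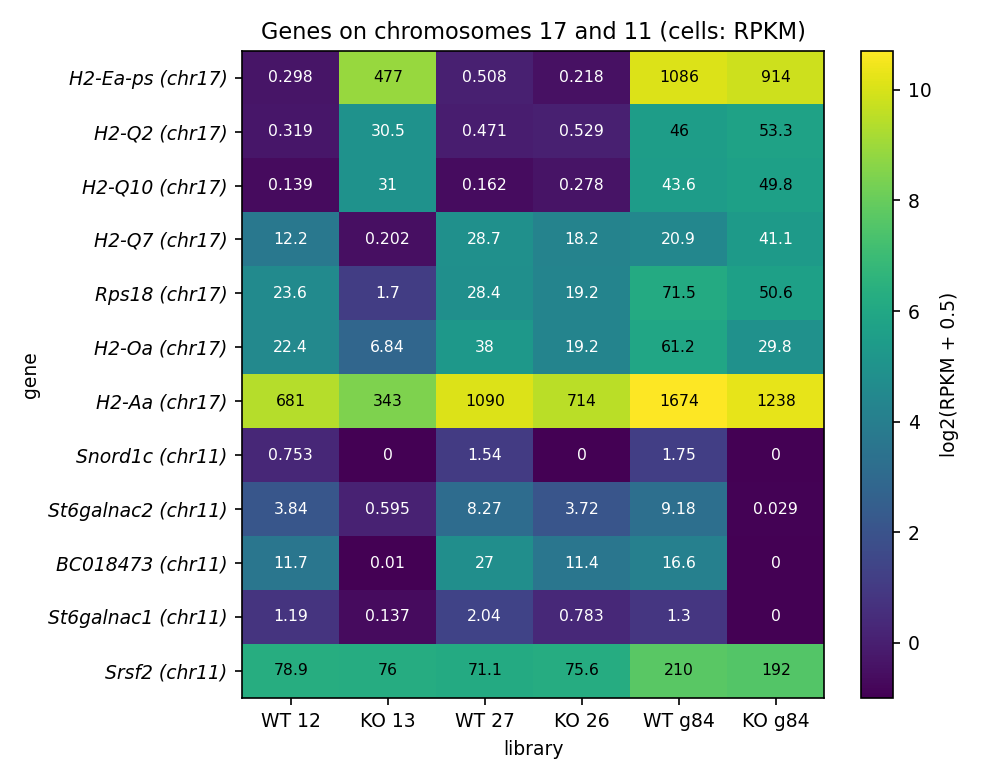
RPKM of 7 genes of chromosome 17 and 5 genes of chromosome 11 in each library, with colour for log2(RPKM + 0.5). H2-Ea-ps is high in KO 13, WT g84 and KO g84, Rps18 is low in KO 13 alone, and BC018473 is near 0 in KO 13 and KO g84, while Srsf2, a neighbour of the 4 genes of chromosome 11, is not.

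Ribosomal protein genes had 32 of 36 members lower and a relative median of -0.18. The members with the smallest p were Rpl3, which was higher at 1.96 ± 0.23 against 1.37 ± 0.26 RPKM, and Rps18, at 23.8 ± 24.8 against 41.1 ± 26.4 RPKM (SD, n = 3 each), whose value in KO 13 was 1.70 RPKM. Camera gave an adjusted p of 0.0286, and adjusted p = 0.940 with an estimated correlation. The call was lost without WT 12 (0.0920), WT g84 (0.237), KO 26 (0.149) or KO g84 (0.104), and the relative median was -0.05 without WT g84, -0.08 without KO 26 and -0.33 without KO g84. Adjusted over the list alone with the pairs, 18 members passed as lower and 1 as higher. Members of this family have many near-identical copies, and how the counting treated them is not stated. Nuclear-encoded genes of oxidative phosphorylation had 33 of 35 members lower (relative median -0.13, camera adjusted p = 0.0981 with genotype alone, 0.00148 after median centring and 0.000223 with the pairs, adjusted p = 0.940 and 0.75 with an estimated correlation), with Cox6c at 45.3 ± 21.8 against 59.7 ± 27.4 RPKM.

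The remaining lists were not called with all 6 libraries and the deposited scaling. Cholesterol and lipid genes had 19 of 21 members lower (camera adjusted p = 0.295), with Mylip at 20.8 ± 7.40 against 28.4 ± 12.7 RPKM. Interferon-stimulated genes had 20 of 30 members lower (0.421), with Ifi44 at 16.3 ± 15.9 against 9.39 ± 12.5 RPKM. They were called higher without KO 13 (4.02e-07) and without WT 27 (4.53e-05), and lower without KO 26 (0.00183). Immediate early genes had 12 of 22 members lower (0.370), with Egr2 at 4.65 ± 2.68 against 6.82 ± 3.45 RPKM (SD, n = 3 each), and adjusted over the list alone 1 passed as higher and 5 as lower with the pairs. Genes of heat shock and cell dissociation had 6 of 11 members higher (0.190, and 0.0494 after median centring). Non-polyadenylated and nuclear RNA had 15 of 24 members lower (0.856), but was called in each fit without 1 library, with a relative median from -1.55 without WT g84 to 1.71 without KO g84.

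Genes of several other cell types were higher in KO. All 15 neutrophil genes were higher, with a relative median of 0.98 (camera adjusted p = 8.10e-25, and adjusted p = 0.397 with an estimated correlation). S100a8 stood at 587 RPKM in KO g84 and between 56.6 and 146 RPKM in the other 5 libraries, and S100a9 at 560 RPKM in KO g84 and between 52.5 and 150 RPKM elsewhere. By pair the relative median of the neutrophil genes was 0.20, -0.13 and 2.89, and without both g84 libraries the list was no longer called (0.173) and S100a8 and S100a9 turned to -0.39 and -0.31. T cell genes had 16 of 19 members higher (2.77e-12, and adjusted p = 0.397 with an estimated correlation). Its 2 most abundant members, Cd2 and Lck, which B cells also express, were lower, at 61.3 ± 27.1 against 76.1 ± 26.4 RPKM and 19.4 ± 11.1 against 29.6 ± 18.7 RPKM (SD, n = 3 each). Without WT g84 the T cell list was not called (0.123), and its relative median was 0.16 there, 0.21 without KO 26 and 0.96 without WT 27 or KO g84. Monocyte and macrophage genes had 15 of 20 members higher (0.000338, and adjusted p = 0.940 with an estimated correlation), with Lyz2 at 241 ± 133 against 186 ± 96.6 RPKM. Hmox1, the haem-degrading enzyme, stood at 67.9 ± 32.8 against 36.3 ± 15.2 RPKM, at least 1.66-fold higher in each pair, and passed by voom with the pairs (adjusted p = 0.00161). The median of the monocyte and macrophage list turned without WT g84 (-0.15) and without KO 26 (-0.24), and the call was lost without WT 12 (0.254).

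NK cell genes had 9 of 11 members higher (5.12e-05, and adjusted p = 0.706 with an estimated correlation), and their median turned without WT g84 (-0.13), while the call was lost without KO 26 (0.320), without both g84 libraries (0.0659) and by voom with the pairs (0.0635). Megakaryocyte and platelet genes had 4 of 5 members higher (0.00830, and adjusted p = 0.678 with an estimated correlation), and were lost without WT 12 (0.0949), WT g84 (0.370), KO 26 (0.0935), KO g84 (0.104) or both g84 libraries (0.237), and by voom with the pairs (0.0914). Dendritic cell genes had 6 of 10 members higher and were not called (0.370), but were called higher without WT 27 (2.17e-06) or KO g84 (0.0314) and lower without WT g84 (0.0320). The erythroid list had 2 tested members, the stromal and endothelial list 3 and the immunoglobulin list 1, too few for the test. The 4 tested sex-linked genes were lower in KO (5.12e-07, and adjusted p = 0.397 with an estimated correlation), through KO g84 alone: without it the relative median was 0.32, and the call was also lost with the pairs (0.383) and with a term for the g84 libraries (0.192).

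**Figure D4:**
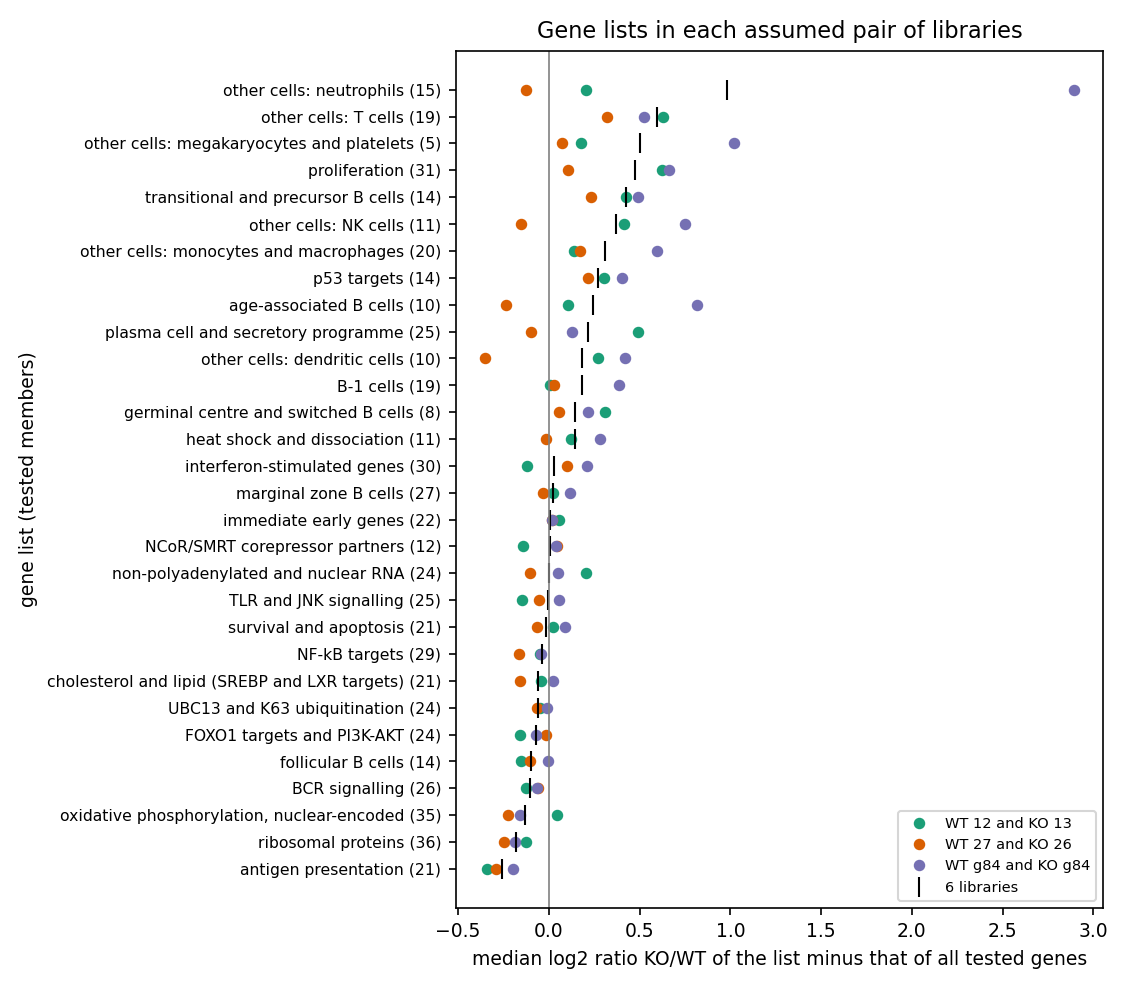
Median log2 ratio of KO to WT of each tested gene list less that of all tested genes, in each assumed pair (coloured points) and over the 6 libraries (black bars), with the number of tested members after the name. The sex-linked list is left out. Proliferation genes lie near 0.63 and 0.66 in 2 pairs and at 0.10 in the pair 27 with 26, and neutrophil genes reach 2.89 in the g84 pair.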

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

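All tests in this part were chosen after the results were seen. Xist, at 60.3 RPKM, and Tsix, at 18.1 RPKM, stood out in KO g84 as a signal outside the genes compared, against at most 0.082 and 0.15 RPKM in any other library. The 4 tested Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, were at 0 to 0.011 RPKM in KO g84 and between 5.59 and 55.0 RPKM in the other 5 libraries. Although the labels give no sex, these values mark KO g84 as female and the other 5 libraries as male. The g84 pair thus sets a female KO against a male WT. Its ratios, which also enter the fits with the pairs, may hold a sex difference beside that of genotype. Tsix overlaps Xist on the other strand and the strand setting of the counting is not stated, so their reads cannot be separated.

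Cd19 was lower in KO in each assumed pair. A lower share of B cells would have lowered other B cell genes alike, but the lower quartile of the log2 fold changes of 26 genes of B cell receptor signalling was -0.28, against -0.96 for Cd19. Scaling of the deposited values is argued against by a log2 fold change of -0.85 after median centring with the pairs (95% interval -1.06 to -0.64). The ratio of KO to WT was at most 0.566 in the 3 pairs, near the 0.5 that the loss of 1 of 2 alleles would give, so a Cd19 allele interrupted by the Cre insertion is a candidate explanation. The labels do not say whether the WT mice carried Cre, so this and an effect of the loss of GPS2 on Cd19 both stay open.

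The antigen presentation list was lower in KO. Different MHC haplotypes of KO and WT within a pair could lower it, since H2-Ea-ps differed between WT 12 and KO 13, but in the 2 pairs with the same state of H2-Ea-ps the relative median was still at most -0.20, with 21 of 21 members lower in the pair 27 with 26 and 13 of 21 in g84. By pair, the 14 members on chromosome 17 had relative medians of -0.62, -0.29 and -0.33 and the 7 elsewhere -0.26, -0.30 and -0.07, with 5, 7 and 4 of these 7 lower, which keeps a haplotype difference open as part of the drop. A lower share of B cells cannot be told apart either, since the upper quartile of the list was -0.198 and the median of the B cell receptor signalling list -0.21, so the lists overlap. An effect of the loss of GPS2 stays open and was not tested apart from these.

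The proliferation list was higher in KO. Argued against as the whole cause are granulocyte precursors in KO g84, by a relative median of 0.63 in the pair 12 with 13, where the neutrophil list stood at 0.20 with 14 of 15 members higher, and a library kit that differs between the series, by 0.36 within the numbered and 0.66 within the g84 libraries. RPKM are scaled to depth already, so sequencing depth could act only beyond that scaling. Such an effect cannot be told apart by sign. KO had fewer reads than WT in the pairs 12 with 13 and g84 (KO over WT 0.891 and 0.756). In the pair 27 with 26, where it had more (1.17), the median was 0.10 with 20 of 31 members higher. T cells left after the isolation stay open as well, since the T cell list had a relative median of 0.32 in the pair 27 with 26, where the proliferation list moved least, and of the CD3 genes Cd3d and Cd3e were higher in KO in all 3 pairs, Cd3g in 2 and Cd247 in g84 alone. More cycling B cells without GPS2 may also account for it, and these libraries do not separate the explanations.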

How the results depend on the processing

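The choice of alternatives was fixed before the data were examined, except for the fits with voom, those without both g84 libraries or without KO g84 together with the pairs, the block with centring, and the list tests with the block. No paired analysis was possible from the labels alone because the titles share only the tag g84, so the replicate block of 3 assumed pairs rests on neighbouring title numbers. Gps2 stayed lower under all 25 alternatives. It passed with the block (-1.59, adjusted p = 0.0421), with the block and centring (-1.48, 0.0166), by voom with the block (-1.50, 0.00118), without both g84 libraries with the block (-1.52, 0.00864) and without KO g84 by voom with the block (-1.37, 4.43e-07). Leaving out 1 library moved it from -1.95 to -1.16 with no pass. The count of genes, 0 with genotype alone, was 1 (1 lower) with sample quality weights and with the block, 4 (3 higher, 1 lower) with the block and centring, 120 (90 higher, 30 lower) by voom with the block, 5 (2 higher, 3 lower) without both g84 libraries with the block, and 275 (207 higher, 68 lower) without KO g84 by voom with the block. Leaving out 1 library gave 0 to 9 genes (0 to 6 higher, 0 to 3 lower). In the other 16 alternatives the count stayed at 0, among them both pseudocounts, both filters and the 3 scalings. The 12 lists fell to 0 with an estimated correlation, with fry, and with the block and an estimated correlation, and leaving out 1 library gave 8 to 14 lists. The block of pairs changed no other call than those given with the results.

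Of 56 named genes under these alternatives, 1323 of 1335 values kept their direction, and the 12 others fall on 6 genes that passed in no fit with genotype alone. With sample quality weights they were Il7r (-0.66), S1pr2 (-0.22), Lyz2 (-1.10) and S100a8 (-0.046). Blk (0.015) turned without WT g84 and Lyz2 (-0.076) without KO 26, and over the 6 fits without 1 library they ranged from -0.82 to 0.015 and from -0.076 to 0.80. S100a9 and S100a8 turned without both g84 libraries (-0.31 and -0.39, with or without the block) and without KO g84 by voom with the block (-0.13 and -0.20). Among called lists, NK cells (-0.13) and monocytes and macrophages (-0.15) turned without WT g84, monocytes and macrophages (-0.24) without KO 26, and sex-linked genes without KO g84 (0.32) and without both g84 libraries (0.12). Without 1 library these lists ranged from -0.13 to 0.88, from -0.24 to 0.93 and from -2.54 to 0.32. The cause was not tested, except that leaving out KO g84 removes the library with Y-linked genes near 0 and high neutrophil genes. Summing transcripts of 1 symbol changed nothing, since the table has 1 per symbol. Depth limits low genes, since 1 read is worth up to 0.0595 RPM.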

Other observations

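The fits with genotype alone, with the block of pairs and with a term for the g84 libraries were fixed before the data were examined, and the tests of explanations in this part were written down after the results were seen. Among the 120 genes of the voom fit with the assumed pairs, 22 lie on any of the gene lists, 7 of them on the proliferation list and 5 on lists of other cell types. The lists hold only some genes of each kind. A called gene outside them may still come from cycling cells or from another cell type. Outside the lists, Ms4a6b, of the MS4A family of membrane proteins, stood at 62.9 ± 24.6 RPKM in KO and 22.1 ± 8.71 RPKM in WT (SD, n = 3 each), at least 2.42-fold higher in each pair, with an adjusted p of 0.000221 by limma's voom. Lower in KO were Gpr183, the oxysterol receptor that guides B cells within the spleen, at 22.7 ± 6.12 against 45.7 ± 15.3 RPKM (0.0270), and Sh2b2, a signalling adaptor, at 5.21 ± 2.61 against 10.7 ± 4.53 RPKM (0.0117). Abcb10, a transporter of the mitochondrial inner membrane, stood at 4.10 ± 1.92 against 9.55 ± 3.64 RPKM (0.0185), the zinc finger gene Cxxc5 at 13.6 ± 9.50 against 25.9 ± 19.4 RPKM (0.0185) and Gdpd3 at 56.7 ± 58.2 against 95.4 ± 84.8 RPKM (0.0171). These 6 genes were chosen after their values were seen, and none passed by limma with genotype alone (adjusted p = 1.0 for each) or with the pairs (0.0707 to 0.105), though Ms4a6b passed with the pairs after median centring (0.0166).

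Several genes were present in some libraries and near 0 in others without following genotype. On chromosome 17, H2-Q2 and H2-Q10 stood at 30.5 and 31.0 RPKM in KO 13, 46.0 and 43.6 RPKM in WT g84 and 53.3 and 49.8 RPKM in KO g84, and at no more than 0.53 RPKM in the other 3 libraries, as H2-Ea-ps did. H2-Q7 stood at 0.20 RPKM in KO 13 and between 12.2 and 41.1 RPKM elsewhere. Magi1, on chromosome 6, stood at 4.01 RPKM in WT 12 and 4.002 RPKM in KO 13 and at no more than 0.12 RPKM elsewhere. Ifi44l, on chromosome 3, stood at 6.18 RPKM in KO 13, 22.7 RPKM in WT g84 and 23.1 RPKM in KO g84 and at no more than 0.24 RPKM elsewhere. AI506816 stood at 0.049 RPKM in KO g84 and between 7.28 and 18.0 RPKM in the others, and Prss12 at 0 in KO g84 and between 0.88 and 3.76 RPKM in the others.

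A hypothesis was that genes that follow genotype in every pair lie near each other, as they would if the KO and WT mice differed in inherited segments. Of the 43 genes at least 1.5-fold apart in every pair, 12 gene pairs lay within 1 Mb, against a median of 2 in 10000 random sets of as many genes, with a permutation p of 1e-04, the smallest that these draws can give. Without the 4 genes of chromosome 11, 6 gene pairs lay within 1 Mb against a median of 1 (permutation p = 0.0072), among them Gps2 with Scimp and Cd19 with Gdpd3. H2-Oa with BC051537 is also among the 6, but the transcripts of the pair overlap and can share reads, and without overlapping pairs 5 remained (permutation p = 0.022). Gdpd3 with Mir762, Rgs13 with Rgs18 and Ms4a6b with Gm8369 are the rest. Placement at random is thus argued against. The count ignored direction, and Ms4a6b was higher in KO while Gm8369 was lower. In the other gene pairs named here both genes moved the same way. The random sets were not built around the genes that the design targets, Gps2 and Cd19, or around neighbours of 1 family such as Rgs13 and Rgs18. The p therefore does not test inherited segments. Segments that differ between the mice may be a part of the list, although genes with shared control also lie together.

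For the 4 genes of chromosome 11 a strain variant carried by some of the mice could be a source, since their median log2 ratio was -1.13 in the pair 27 with 26, against -1.70 and -3.18 in the other pairs, while the log2 ratios of Gps2 lay within 0.32 of each other. The smaller drop rests on 1 library, KO 26, so a direct effect of the loss of GPS2 cannot be told apart from such a variant. Reads shared between overlapping transcripts are argued against among the 4 genes, since 0 of them overlap another of the 4. Gps2 lies on the same chromosome, at 69730387, and whether the 4 genes were inherited along with the targeted allele was not tested.

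The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. By limma with genotype alone the real split gave 0 genes, which each of the 10 splits must reach, so this count says nothing about chance. The highest of the others gave 14, and that split, of WT 12, WT 27 and KO 26 against the others, put both g84 libraries together. Up to 5157 genes had an unadjusted p under 0.05 in a split with both g84 libraries on 1 side, which points to a structure of the libraries other than genotype. With the block of pairs the real split gave 1 gene, and with a term for the g84 libraries 0 (1332 unadjusted). For the gene lists, 4 of the 10 splits gave as many as the real 12, and the highest of the others gave 15. Only 4 splits part all 3 assumed pairs, again too few for a share under 0.05. Among them the real split gave 43 genes at least 1.5-fold apart in every pair and the others at most 7, and by voom with the pairs 120 genes against at most 0 in the others, so 1 of the 4 splits gave as many in each case. The count of 43 was made on ratios that were not centred.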
